A study of Mus musculus with 7 samples.

How the data were processed

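RNA from 7 mouse samples was hybridised to 1 array each: WT and Utx KO ESCs, WT and Utx KO MEFs without DOX, WT and Utx KO MEFs with DOX, and Nanog KO fibroblasts carrying the 4 factors on a lentivirus for 8 days. Groups were taken from the labels. The labels' protocols give one growth medium, that of ESCs, for all samples, and name a labelling kit for 3-prime expression arrays, whereas the probe identifiers are those of a whole-transcript gene array. Which of these was used is not given in the sources used here.

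The authors deposited log2 values made with Affymetrix Expression Console and RMA, per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises probes. Software versions and the genome build are not given in the sources used here. The table held 21811 rows and 7 samples with 0 missing values. Array medians were 7.68 to 7.84 on the 6 Utx arrays and 8.55 on the Nanog KO array, and whether the last was normalized with the others is not given in the sources used here. Its differences from the others are given beside the shift. Alignment of array medians was an alternative throughout. Depth has no counterpart on these arrays, and the number of arrays, 1 per condition, limits the precision.

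Rows were named through the platform annotation: 14894 rows had 1 gene symbol, 925 had several and were left out, and 5992 were not listed there and are unnamed here. Gene IDs of 14854 of the named rows were found in the RefSeq table of GRCm38.p6, used for names only, and 0 symbols needed an update. Where a gene had several rows (754 of 13562 genes), the row with the highest mean over the 7 arrays stood for it. For the genes named in a 2-array comparison all rows of a gene had the same sign. No coordinates are printed.

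The choices in this paragraph were made before the data were examined. For 2 arrays, the log2 difference was taken per gene, and genes were counted at 2-fold or more where the higher value exceeded a floor, the 40th percentile of all values (7.34). The 10 genes with the largest difference in each direction are named, and Kdm6a, Kdm6b, Uty, Nanog, Pou5f1, Sox2, Klf4 and Myc are always named, with list members with large differences as examples. Log2 differences are those of the deposited values, also under the floor. For 21 gene lists the median difference over measured members was set against 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Counts of 2-fold members use members above the floor. The 95% interval beside a list median comes from order statistics across its members, which are not replicates. The share of the MEF to ESC distance was the difference from MEFs without DOX divided by the difference between ESCs and those MEFs, over genes at least 4-fold higher in ESCs, within a genotype, and for the Nanog KO array against WT.

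limma 3.58.1 in R 4.3.3 fitted the 6 Utx arrays with context and genotype as additive terms (lmFit, eBayes with a trend), for the 10673 genes whose highest value exceeded the floor. The residual, with 2 degrees of freedom, holds the difference of the genotype effect between contexts, so its p-values ask whether a difference was alike in the pairs and do not measure the spread between cultures. P-values were adjusted by Benjamini-Hochberg at 0.05. With no gene past it, the 10 genes in each direction with the largest smallest-of-pairs difference are named. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

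The fit was tested on simulated data for the genotype contrast with 10673 genes: of 50 changed genes at each size it recovered 7 at a log2 change of 1, 32 at 2, 42 at 4 and 43 at 6, with 11 false calls. The simulated noise was independent between genes and arrays, without the genotype-by-context differences that the real residual holds. These rates check the code and do not give the sensitivity on the real arrays. The list percentile, tested on the ESC comparison with 13562 genes and lists of 30, lay outside the central 95% for 6 of 100 unshifted lists and for 100 of 100 lists shifted by 0.5. Alternatives covered array scaling (aligned medians, quantile normalization), the floor (none, the 60th percentile at 8.48), a threshold of 1.5, the mean over a gene's rows, the variance prior, the block, and sets of arrays. Folds whose lower side lay under the floor are given as at least the fold with that side set to the floor, a rule added after the data were seen. Fits without 1 of the doubted libraries, and list medians over members above the floor, were added after the data were seen. An alternative that leaves out identifiers with cross-hybridisation endings was not run, since no identifier had one.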

Results

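The series measured gene expression with Affymetrix arrays in 7 mouse samples, 1 array per condition. Utx, the product of the X-linked gene Kdm6a, removes methyl groups from lysine 27 of histone H3, and the title of the series concerns its part in reprogramming to pluripotency. Embryonic stem cells (ESCs) of the V6.5 line were profiled as wild type (WT) and as Utx knockout (KO). Mouse embryonic fibroblasts (MEFs) of both genotypes were profiled without and with doxycycline (DOX), the drug that switches on the 4 reprogramming factors Oct4, Sox2, Klf4 and Myc (OSKM). The last array held Nanog knockout fibroblasts that had carried the factors on a lentivirus for 8 days. No condition was repeated, so no 2-array difference below has a replicate check or a p-value, and the number of arrays limits the precision of every value. Values are deposited log2 values, and differences are on the log2 scale.

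Kdm6a was lower in the KO library in each of the 3 contexts. It read 9.12 in WT and 7.97 in KO ESCs, a difference of -1.15. In MEFs without DOX it read 8.22 in WT and 6.32 in KO, a difference of -1.90, and in MEFs with DOX it read 8.93 and 7.57, a difference of -1.36. The Nanog KO array read 9.08. A single probe set spans Kdm6a here, and whether its probes lie in the part removed from the KO allele is not given in the sources used here, so the signal left in the KO cells does not measure functional transcript. Kdm6b, the other active demethylase of this mark, differed by 0.15 in ESCs, 0.52 in MEFs without DOX and 0.44 in MEFs with DOX. The Nanog probe set read 12.28 and 12.59 in the ESCs and 6.56 on the Nanog KO array, against 5.48 in WT MEFs with DOX. Since these WT MEFs already lay below the floor, the probe set did not check that genotype.

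Genes of the Y chromosome differed between the genotypes as well, although the labels call both ESC libraries XY. Uty, the Y-linked relative of Utx, read 8.44 in WT and 3.68 in KO ESCs, and Eif2s3y, a translation factor subunit gene on the Y chromosome, read 8.52 and 4.19. In the MEFs Eif2s3y differed by -3.82 without DOX and by -3.14 with DOX, while Uty differed by -0.39 and 0.07. Kdm5d differed by -1.44 without DOX and by -1.88 with DOX, and in the ESCs, where it read 4.49 and 4.41, by -0.08. It lay under the floor in both ESC libraries and in both MEF libraries without DOX. Xist, the RNA of the inactive X chromosome, read 8.10 in WT and 6.60 in KO ESCs, 11.06 and 9.87 in MEFs without DOX, and 10.90 and 10.98 with DOX.

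**Figure D1:**
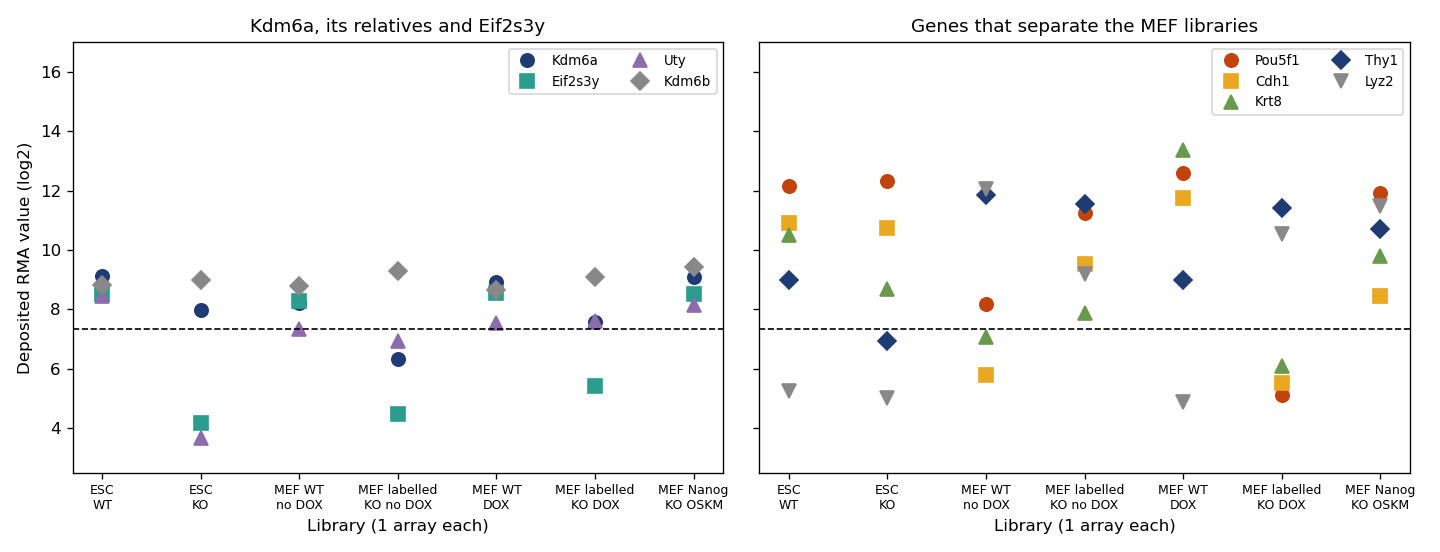
Deposited log2 values (vertical axis) of 9 genes in each of the 7 libraries (horizontal axis, 1 array each), with the floor for low values at 7.34 as a dashed line. Kdm6a lies lower in the KO than in the WT library of each pair, whereas Pou5f1 and Cdh1 are high in the library labelled KO without DOX and low in the library labelled KO with DOX.

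Genes that differed with DOX in the WT MEFs often differed the other way between the KO MEF libraries as labelled. Pou5f1, which encodes the factor Oct4 that DOX induces, read 8.19 in WT MEFs without DOX and 12.59 with DOX. In the library labelled KO without DOX it read 11.26, and in the library labelled KO with DOX it read 5.12. Over all 21811 array rows, WT MEFs without DOX correlated with the library labelled KO with DOX at r = 0.972 and with the library labelled KO without DOX at r = 0.921, and WT MEFs with DOX correlated with these at r = 0.842 and r = 0.864, across rows that are not independent replicates. As whole profiles, both KO libraries were thus nearer to WT MEFs without DOX, the one labelled KO with DOX most of all. Both libraries are therefore named below by their labels only, and each direction drawn from them holds for the labels as given.

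In ESCs, the KO library had lower levels of mesenchymal and fibroblast genes than the WT library, while the pluripotency genes stayed high in both. With 1 library of each genotype, loss of Utx cannot be told apart from another difference between the cultures. Of the 30 mesenchymal and fibroblast genes above the floor, 21 were 2-fold or more lower in KO ESCs and 0 were higher. The list median over 41 measured members was -1.29 (95% interval across members -2.20 to -0.79), at percentile 0.0 of 10000 random lists. Lox, the enzyme that crosslinks collagen, read 11.51 in WT and 7.96 in KO ESCs. Postn, a secreted matrix protein, differed by -3.26, Cnn1, an actin-binding protein of smooth muscle, by -3.25, and Prrx1, a mesenchymal transcription factor, by -3.21. Other members differed little: Fn1 by -0.30 and Zeb1 by 0.03.

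Across 8598 genes above the floor in ESCs, 56 were 2-fold or more higher and 273 lower in the KO library. After Uty and Eif2s3y, the lowest were Cav1, the coat protein of caveolae, at least 8.2-fold lower, the signalling ligand Tgfb3, at least 4.1-fold lower, and Timp2, an inhibitor of matrix metalloproteinases, at 12.3-fold lower. The next were Actg2, Lox, Ccdc80, Bgn and Penk, with Lox at 11.7-fold lower and Penk at least 5.6-fold lower. The 10 genes with the largest difference upwards were Actn3, Hhip, Notum, Dpp4, Slc27a2, Slc7a11, Inhbb, Msc, Cpsf4l and D1Pas1. Among these Actn3, a muscle actinin, was at least 3.0-fold higher, Hhip, which binds hedgehog ligands, at least 1.3-fold higher, and Notum, which inactivates Wnt proteins, 4.1-fold higher.

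The pluripotency list outside the 4 factors had a median difference of 0.24 in ESCs (0.12 to 0.38), at the top of 10000 random lists. Of its 41 members above the floor, 1 was 2-fold higher, 1 was 2-fold lower and 39 lay within 2-fold. Eras differed by 1.28 and Lefty2 by -1.94, whereas Nanog differed by 0.32 and Esrrb by 0.22. The factors themselves were close, with Pou5f1 at 0.18, Sox2 at 0.44, Klf4 at 0.11 and Myc at 0.25. The naive pluripotency list had a median of 0.32 with 15 of 15 members within 2-fold, and the primed list a median of -0.11. Epithelial genes had a median of -0.23, with 5 of 18 members above the floor lower, among them Krt18 at -2.15 and Krt8 at -1.83. The cell cycle list had a median of 0.16, and all 30 members lay within 2-fold.

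In MEFs without DOX, the library labelled KO held less macrophage RNA and more RNA of epithelial and cell cycle genes than the WT library. The leukocyte and macrophage list had a median difference of -2.87 (-3.33 to -2.60, percentile 0.0), with 16 of 17 members 2-fold or more lower. Its median level was 9.40 in WT and 6.29 in the library labelled KO. Adgre1, the macrophage surface marker F4/80, was at least 6.0-fold lower, and Lyz2, a lysozyme of macrophages, read 12.06 and 9.19. The epithelial list had a median of 0.66 (0.38 to 1.02), with 8 of 15 members above the floor higher and 1 lower, and the higher ones included Itgb4 at 4.03 and Cdh1, the adhesion molecule E-cadherin, at 3.75. Cell cycle genes had a median of 0.96 (0.71 to 1.18), with 14 of 30 members 2-fold or more higher, such as Mcm7 at 1.92 and Ccne1 at 1.89.

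The same library had lower values for mesenchymal genes (median -0.59, 12 of 40 members above the floor lower, 0 higher) and interferon-stimulated genes (median -0.92, 8 of 14 lower). Pluripotency genes outside the 4 factors had a median of 0.52 (0.22 to 0.70), with 5 of 14 members above the floor 2-fold or more higher. Gdf3 differed by 3.10, Nanog by 2.39 and L1td1 by 2.31, and Pou5f1 by 3.06, while Sox2, at 0.29, stayed below the floor in both libraries. Hox genes, which pattern the body axis, had a median of -0.51, with 6 of 11 members above the floor lower, among them Hoxc6 at -1.63 and Hoxc8 at -1.57.

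Over 9253 genes, 466 were 2-fold or more higher and 882 lower in the library labelled KO without DOX. The median gene differed by -0.11, and with the array medians aligned the split was 677 higher and 685 lower. The 10 largest differences upwards were in Aldh3a1, Apela, Shisa3, Avil, Pllp, 1700019D03Rik, Itgb4, Tgm3, Podxl and Cdh1, with the aldehyde dehydrogenase Aldh3a1 at least 10.9-fold and Cdh1 at least 4.6-fold higher, all 10 being under the floor in WT. The 10 largest downwards were in Ccl3, Lilr4b, Adgre1, Prg4, Ms4a6c, Clec4e, Gjb2, Clec4a1, Ch25h and Ccl5, with the chemokine Ccl5 at least 10.2-fold lower.

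With DOX, the WT MEFs had lower fibroblast and higher epithelial genes than without, while most pluripotency genes stayed low. Of 30 epithelial genes above the floor, 28 were 2-fold or more higher with DOX, 1 was lower and the list median was 3.31 (2.69 to 4.70, at the top of the random lists). The desmosomal protein gene Dsp differed by 6.36, the keratin gene Krt8 by 6.29 and Cdh1 by 5.95, against -2.39 for Cdh3. Mesenchymal genes had a median of -2.87 (-3.36 to -2.20, percentile 0.0), with 34 of 40 lower and 0 higher. Postn differed by -6.99, Cnn1 by -6.38 and Pdgfrb by -5.52, whereas Dcn differed by 0.29 and Prrx1 by -0.47. The leukocyte and macrophage list moved with them, at a median of -4.37 with 16 of 17 members lower, its level being 9.40 without and 5.36 with DOX.

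The pluripotency list outside the 4 factors had a median of 0.26 with DOX in WT MEFs (0.04 to 0.49, percentile 99.6). Of its 14 members above the floor, 8 were 2-fold or more higher and 2 lower. L1td1, an RNA-binding protein gene, differed by 3.56, Tfcp2l1 by 3.02, Fgf4 by 2.89 and Tet2 by 2.22, against -2.36 for Tet1 and -1.90 for Klf2. Nanog differed by 0.05 and Esrrb by 0.49, both below the floor on both arrays. Of the factors, Pou5f1 differed by 4.40, Myc by 1.22, Sox2 by 0.13 and Klf4 by -0.11. Interferon-stimulated genes had a median of -1.15, with 10 of 14 members lower, and imprinted genes a median of -1.60, with 12 of 19 lower and 1 higher.

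Over 9524 genes, 1134 were 2-fold or more higher and 1304 lower with DOX in WT MEFs. The 10 largest differences upwards were in Ly6g6c, Cyp4f39, Cwh43, Nccrp1, Alox12b, Aldh3a1, Mall, Gpr50, Podxl and Krt16, each at least 15.4-fold, with all 10 under the floor without DOX. Alox12b and Cyp4f39 encode enzymes that make lipids of the skin barrier, and Krt16 encodes a keratin of stratified epithelia. The 10 largest downwards were in Lyz2, Postn, Aspn, Penk, Tnmd, Fgf7, Abi3bp, Sfrp2, Cnn1 and Ccl3, each at least 11.7-fold, with all 10 under the floor with DOX.

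In the KO MEFs as labelled, DOX went with lower epithelial genes and higher mesenchymal genes. The epithelial list had a median of -0.70 (-1.35 to -0.40, percentile 0.0), with 10 of 14 members above the floor lower and 1 higher. The pluripotency list had a median of -0.49 (-0.95 to -0.28), with 6 of 14 lower and 0 higher, but with the floor at the 60th percentile its sign turned, to 0.12. Pou5f1 differed by -6.14. Mesenchymal genes had a median of 0.61 (0.41 to 0.74), with 7 of 40 higher and 0 lower, and the leukocyte and macrophage list had a median of 0.90, with 7 of 10 members above the floor higher. Cell cycle genes had a median of -0.58, with 5 of 30 lower. Sox2 differed by 0.49, Klf4 by -1.23 and Myc by -0.46.

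Over 9119 genes, 621 were 2-fold or more higher and 267 lower in the library labelled KO with DOX than in the one labelled KO without DOX. The median gene differed by 0.13, and aligned medians gave 481 higher and 378 lower. Below Pou5f1 came Aldh3a1, Shisa3, Apela, Avil, Tgm3, Pllp, Cdh1, Ehf and Podxl, with Aldh3a1 at least 10.9-fold and Cdh1 at least 4.6-fold lower. The largest differences upwards were in Cxcl15, Saa3, Pgm5, Tnmd, Rspo3, Lgr5, Car3, Myl1, Npr3 and Reg3g, with the chemokine Cxcl15 at least 3.7-fold and Reg3g at least 1.1-fold higher. Across 10673 genes the DOX difference in the KO MEFs as labelled correlated with that in the WT MEFs at r = -0.53 and rho = -0.46, with genes that are not independent replicates and no array shared. Of 637 genes 2-fold or more apart in both genotypes, 599 (94.0%) went in opposite directions.

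**Figure D2:**
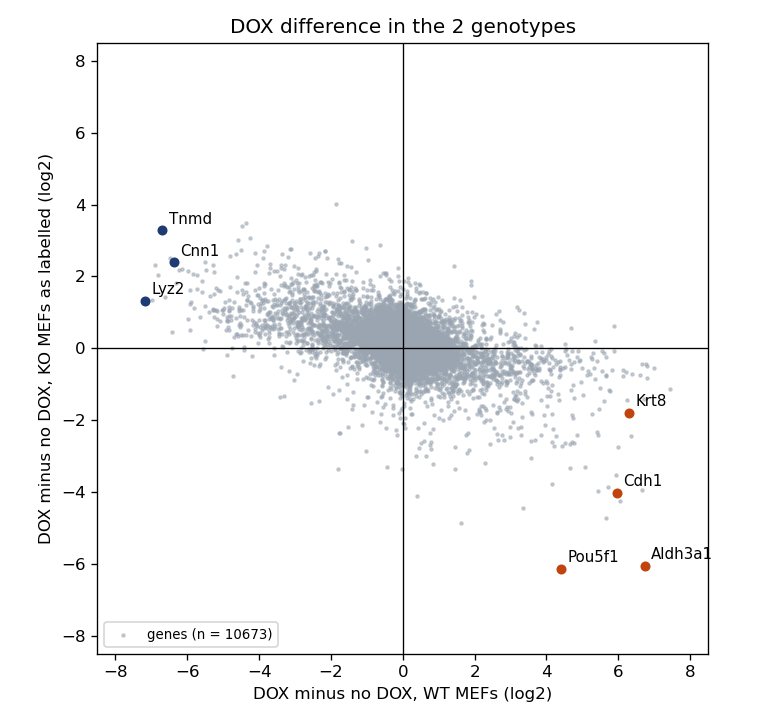
Each point is 1 of 10673 genes above the floor, with the log2 difference between DOX and no DOX in WT MEFs on the horizontal axis and in KO MEFs as labelled on the vertical axis. The points slope downwards (r = -0.53), and Pou5f1 lies at 4.40 and -6.14.

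The difference between the genotypes in the DOX response, labelled KO minus WT, followed from these values. Its median was -4.22 for epithelial genes (-5.53 to -3.31), with 28 of 30 members above the floor at -1 or less. For pluripotency genes outside the 4 factors it was -0.95 (-1.61 to -0.53), with 12 of 17 at -1 or less and 3 at 1 or more. For mesenchymal genes it was 3.36 (2.75 to 4.30), with 35 of 40 at 1 or more, and for leukocyte and macrophage genes 5.22. Restricted to members above the floor, a choice made after the data were seen, the pluripotency median was -2.28. With 1 array per condition this difference was not tested.

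With DOX, fibroblast genes were higher and epithelial genes lower in the library labelled KO than in the WT library. Epithelial genes had a median difference, KO minus WT, of -3.58 (-4.48 to -2.92, percentile 0.0), with 28 of 30 members above the floor lower, such as Krt8 at -7.27 and Dsp at -6.73. Mesenchymal genes had a median of 2.74 (1.99 to 3.52, at the top of the random lists), with 34 of 40 higher, such as Postn at 6.80 and Lum at 6.49. The pluripotency list had a median of -0.19 (-0.49 to 0.02), with 8 of 15 members above the floor lower and 3 higher. L1td1 differed by -3.84, Fgf4 by -3.31 and Pou5f1 by -7.48, against 2.56 for Tet1. Sox2 differed by 0.66, Klf4 by -0.39, Myc by -1.88 and Nanog by 0.11.

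Over 9572 genes, 1371 were 2-fold or more higher and 1159 lower in the library labelled KO with DOX than in WT MEFs with DOX. Serpina3n, Dpt, Sfrp2, Postn, Aspn, Ccn3, Tnmd, Igsf10, Abi3bp and Lum had the largest differences upwards, each at least 9.5-fold. Ly6g6c, Pou5f1, Mall, Krt8, Krt16, Cyp4f39, Ceacam1, Aldh3a1, Cwh43 and Nccrp1 had the largest downwards, each at least 15.4-fold, and in all 20 the lower side lay under the floor. The leukocyte and macrophage list had a median of 2.02, with 8 of 10 members above the floor higher. Imprinted genes had a median of 1.23, with 12 of 19 higher and 1 lower.

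**Figure D3:**
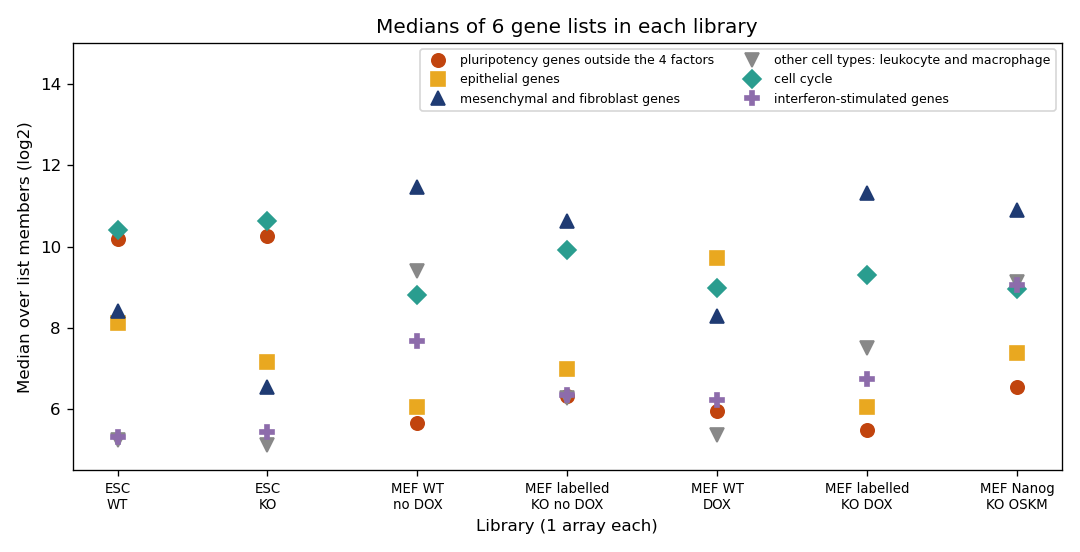
Median log2 value over the measured members of 6 gene lists (vertical axis) in each library (horizontal axis, 1 array each). The epithelial list reads 9.72 and the mesenchymal list 8.30 in WT MEFs with DOX, against 6.05 and 11.32 in the library labelled KO with DOX, and the Nanog KO array has a higher array median than the others.

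Measured against the distance from MEFs to ESCs, WT MEFs with DOX had gone a small part of the way for pluripotency genes. For the epithelial genes at least 4-fold higher in ESCs they were at about ESC levels or beyond. Over 38 pluripotency genes at least 4-fold higher in ESCs, the median share of the log2 distance was 5.4% (0.7% to 13.8%). It was 50% or more for 4 of them, L1td1 at 90.3%, Tet2 at 78.9%, Fgf4 at 63.3% and Etv5 at 56.6%, and below 0 for 12. With the KO arrays as end points the median was -8.3%, a change of sign. Over 14 epithelial genes the median share was 131.9% (96.1% to 178.5%). In the library labelled KO with DOX the pluripotency median was -14.8% (-23.6% to -5.9%), with 32 of 38 genes below 0, counted from the library labelled KO without DOX, but -2.0% with the WT arrays as end points. The epithelial median over 7 genes was -33.4%.

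The Nanog KO fibroblasts, set against WT MEFs with DOX, had higher mesenchymal, macrophage and interferon-stimulated genes and lower epithelial genes. This array had a median log2 value of 8.55, against 7.68 to 7.84 on the other 6, and the median gene above the floor differed by 0.76, so its differences are set beside that shift. It also differed in cell line and in the way the factors were delivered. Interferon-stimulated genes had a median difference of 2.83 (2.26 to 3.80, at the top of the random lists), with 22 of 22 members above the floor higher, led by Trim30a at 5.90 and Ifit3 at 4.79. Mesenchymal genes had a median of 2.58, with 33 of 39 higher, and the leukocyte and macrophage list one of 3.42, with 13 of 13 higher. Epithelial genes had a median of -1.74 (-3.14 to -1.31), with 26 of 30 lower, such as Cldn7 at -4.35 and Spint1 at -4.07.

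On the Nanog KO array Pou5f1 differed by -0.68, Sox2 by 1.10, Klf4 by 1.56 and Myc by -1.39 from WT MEFs with DOX. The pluripotency list had a median of 0.52, which lies below the shift of the median gene at percentile 2.2, and -0.22 with array medians aligned. Etv5 differed by -4.55 and Fgf4 by -2.56. Its median share of the distance from WT MEFs to WT ESCs was 17.6%, and 1.6% with medians aligned. Of 10833 genes, 4032 were 2-fold or more higher and 599 lower, and with medians aligned 1281 and 1299. The largest differences upwards were in Lum, Ogn, Vsnl1, Aspn, Hmcn1, Dpt, Penk, Igsf10, Gpc3 and Pamr1, all under the floor in WT MEFs with DOX. Lum, a collagen-binding proteoglycan, was at least 47.5-fold higher, or 28.1-fold with the shift removed. The largest downwards were in Ly6g6c, Cyp4f39, AU018091, Cwh43, Krt16, Tgm1, Alox12b, Mal2, Cpn1 and Klk10, each at least 9.7-fold.

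The genotype difference shared by the 3 contexts was estimated with limma from 6 arrays. Of 10673 genes tested, 0 passed an adjusted p of 0.05 and 188 had an unadjusted p under 0.05. All 3 pairs differed in 1 direction for 2295 genes (21.5%), against 25% by chance. Among these, by the smallest of the 3 pairs, the largest differences were lower values of Eif2s3y, Ptgs2, Hoxc6, Kdm6a, Tmem62, Slco2a1, Adgrg1, Fxyd5, Serpinb9b and Lgals9 in KO. Eif2s3y had a log2 difference of -3.76 (standard error 0.45), Ptgs2, the inducible prostaglandin synthase, one of -2.02 (0.23), and Kdm6a one of -1.47 (0.26), each with a limma adjusted p of 0.995. The opposite direction was led by D17H6S56E-5, Evc, Ano3, Xkr5, Nnat, Syndig1, Pclaf, Gli2, Spats2l and Enox1, with D17H6S56E-5 at 1.41 (0.26). Without the MEF DOX pair 4 genes passed, all lower in KO: Penk, Cnn1, Inhba and Glipr1, named after their values were seen.

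By camera with a preset correlation, cell cycle genes were higher in KO (median 0.54 over 30 genes, adjusted p = 4.93e-17) and epithelial genes lower (median -0.96, adjusted p = 8.33e-06), as were the Y-linked genes and Xist (adjusted p = 0.000176). Each call was lost with an estimated correlation, at an adjusted p = 0.829 for all 3 lists. The epithelial value was not shared by the contexts, since the list medians were -0.23 in ESCs, 0.66 in MEFs without DOX and -3.58 in MEFs with DOX. Of the list members, Kdm6a and 1 member of the Y-linked list passed when p-values were adjusted over the list alone, and 0 members of the other 19 lists did.

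No gene was called for a DOX difference shared by both genotypes at this threshold. The residual holds the opposed DOX differences in WT and in KO as labelled. Calls of 0 genes therefore do not show that no difference was shared. Of 10673 genes, 0 passed in limma, 100 had an unadjusted p under 0.05, and both pairs went in 1 direction for 35.6% of genes against 50% by chance. Srgn, Cdsn, Serpinb9b, Ptprz1, Mme, Lmo7, Susd2, Slc39a8, Endod1 and Ccdc68 had the largest upward differences by the smaller of the 2 pairs, with Cdsn, a protein of cornified epithelia, at 1.83 (standard error 0.27). Sostdc1, E330013P04Rik, Gda, Gatm, Apod, Nnat, Pcx, Col15a1, Slc43a2 and Cxcl14 had the largest downwards, with Gatm at -1.87 (0.36), and each of these 20 genes had a limma adjusted p of 1. With a preset correlation camera called mesenchymal genes lower (adjusted p = 1.08e-07), leukocyte and macrophage genes lower with them (adjusted p = 2.62e-07), epithelial genes higher (adjusted p = 4e-05) and cell cycle genes lower (adjusted p = 4.99e-05), but with an estimated correlation each had an adjusted p = 0.738. The p53, imprinted, interferon-stimulated, naive pluripotency and pluripotency lists were also called lower at the preset correlation, from adjusted p = 0.0052 to adjusted p = 0.0345, and with an estimated correlation each had an adjusted p = 0.738. Most of these calls average opposed medians in WT and in KO as labelled: mesenchymal -2.87 and 0.61, leukocyte and macrophage -4.37 and 0.90, epithelial 3.31 and -0.70. Imprinted (-1.60 and 0.40), interferon-stimulated (-1.15 and 0.66) and pluripotency genes (0.26 and -0.49) were opposed too. Cell cycle genes had 0.01 and -0.58, and the p53 (-0.41 and -0.21) and naive lists (-0.03 and -0.49) were lower in both. Fits without 1 of the KO MEF libraries leave a single WT array on one side, so they say nothing on a difference shared by both genotypes.

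ESCs differed from MEFs without DOX in pluripotency, mesenchymal and cell cycle genes in both genotypes. In limma 0 of 10673 genes passed an adjusted p of 0.05, 3104 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0553. In both pairs 986 genes were 2-fold or more higher in ESCs and 1371 lower, and 80.1% of genes went in 1 direction in both. Zfp980, Nr0b1, Tdgf1, Dppa5a, Lncenc1, Zfp640, Sox2, Epp13, AU018091 and Esrrb led upwards, with Dppa5a at 7.89 (standard error 0.56) and Sox2 at 6.15 (0.31), both with a limma adjusted p of 0.0553. Fmod, Ptn, Dcn, Lum, Igfbp4, Kcnma1, Col6a3, Fgf7, Dlk1 and Igfbp5 led downwards, with Dcn, the proteoglycan decorin, at -6.04 (0.33).

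Of 41 pluripotency genes tested between ESCs and MEFs, 36 passed as higher in ESCs when adjusted over the list alone, as did 24 of 30 cell cycle genes and 12 of 15 naive pluripotency genes. Only 3 of 40 mesenchymal genes passed as lower. By size, 34 of 40 mesenchymal genes above the floor were 2-fold or more lower in ESCs in WT and 36 of 40 in KO as labelled, with 0 higher in either. Cell cycle genes were less alike: 26 of 30 were 2-fold or more higher in ESCs in WT (median 1.65) and 7 of 30 in KO as labelled (median 0.76). Camera with a preset correlation gave adjusted p = 1.76e-20 for the pluripotency list, adjusted p = 7e-10 for mesenchymal genes, whose median was -3.04, and adjusted p = 1.17e-09 for cell cycle genes. With an estimated correlation these became an adjusted p = 0.427, an adjusted p = 0.622 and an adjusted p = 0.53. Leukocyte and macrophage genes were lower beside them (median -2.64, adjusted p = 0.0121 at the preset and adjusted p = 0.664 at the estimated correlation). At the preset correlation camera also called partners of Utx (adjusted p = 0.00056) and the H3K27 and Polycomb list (adjusted p = 0.00637) higher in ESCs. It called naive pluripotency and germ cell genes higher, and Hox and imprinted genes lower. None of these calls held in camera with an estimated correlation, at an adjusted p of 0.427 or more. Leaving out the MEF DOX pair gave 3182 genes past the threshold, and leaving out the library labelled KO with DOX gave 3194, a fit added after the data were seen.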

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

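All tests in this part were chosen after the results were seen. The groups hold 1 array each, so the differences between groups below were not tested. Pou5f1 moved in opposite directions with DOX, at 4.40 in WT and -6.14 in KO MEFs as labelled, which differ by -10.54, and the KO minus WT difference went from 3.06 without DOX to -7.48 with DOX, again -10.54 apart. The leukocyte and macrophage list went from -2.87 without DOX to 2.02 with DOX in KO minus WT, 4.89 apart. The mesenchymal list went from -1.29 in ESCs to 2.74 in MEFs with DOX, 4.03 apart.

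Genes that differed with DOX in WT MEFs often went the other way between the KO MEF libraries as labelled, such as Pou5f1 and Cdh1. If the labels are right and loss of Utx blocks the response, genes at least 4-fold higher with DOX in WT (n = 512) should lie at 0 or above in the KO MEFs, but their median was -0.58 (-0.61 to -0.51). That interval runs across genes and holds no spread between cultures. A blocked response with another difference between the KO cultures could give this median too, so it cannot decide. ESC RNA in the library labelled KO without DOX would bring all abundant ESC transcripts, but pluripotency genes gave a median ESC share of 1.4% (0.5% to 4.4%) where Pou5f1 needed 47.4%. An exchange of the 2 labels stays open. Of the 2438 genes 2-fold apart in WT, 82.2% went the other way, which restates the pattern. The library labelled KO without DOX correlated more with WT MEFs without DOX (r = 0.921) than with DOX (r = 0.864). That order cannot decide, since a KO library that had received DOX but responded more weakly than WT could show it too. With exchanged labels limma called 2804 genes between ESCs and MEFs (1299 higher, 1505 lower) and 0 for DOX (1495 instead of 100 at unadjusted p under 0.05), at a median residual SD of 0.268 instead of 0.327, but these fits use the values in which the pattern was found, and another difference between the KO cultures stays open too.

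Fibroblast genes were lower in KO than in WT ESCs. MEFs like those profiled here, mixed into the WT ESC library, would give 1 common share over all MEF genes, but 39.7% of 252 genes at least 16-fold higher in WT MEFs than in KO ESCs gave a share over 4-fold away from the median of 4.8%. Among these genes Cnn1 gave 39.7%, whereas Dcn gave 0.9%, Lum 0.16% and Lyz2 0.14%. Acta2, which lay under the 16-fold limit and so outside this set, gave 63.3%. Lower activity of these genes without Utx could not be separated from a difference between the 2 cultures: the list median in KO minus WT was -0.59 (-0.97 to -0.44) in MEFs without DOX and 2.74 with DOX, and both rest on the doubted labels. Other differentiating or feeder cells in the WT ESC culture were not tested.

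Some Y-linked genes were lower in KO libraries: Eif2s3y in all 3, Uty in the ESCs alone and Kdm5d in the MEFs alone. Kdm5d lay under the floor in both ESC libraries, so a lower KO value could hardly show there. Its difference in MEFs without DOX lay under the floor too. Absence of the Y chromosome from the KO ESCs is a candidate explanation there: Uty lay at percentile 0.06 and Eif2s3y at percentile 0.57 of all values on that array. In the KO MEFs the same explanation stays open, because Uty lay near its WT level (differences of -0.39 and 0.07), 3.27 and 3.94 above its KO ESC value, but close to the floor, while Eif2s3y read 4.46 without and 5.42 with DOX as labelled against 4.19 in the KO ESCs. Low signal cannot tell absence of the chromosome from low expression of its genes, and no other explanation was tested.

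The limma genotype contrast gave 0 genes, and splits of the 6 arrays cannot judge that count. With 10 splits a share under 0.1 cannot be reached, and only some of them keep 1 array of each context on each side, as the real one does. The real count was 0 and the highest other 439. The count of 439 came from 2 splits that set both ESC arrays and 1 of the MEF arrays with DOX against the rest. With context as a block, such a fit is informed only by the gap between the 2 MEF libraries with DOX, so it is not comparable with the real contrast.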

How the results depend on the processing

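Values of 2 arrays have no replicate check, and genes under the floor are limited by background signal. Kdm6a kept its direction and its 2-fold difference in ESCs and in MEFs without and with DOX under aligned medians and quantile normalization. Counts of 2-fold genes stayed within 1.5 times in 27 alternatives and moved further in 9, and 535 alternative list medians stayed within their interval while 46 left it and 11 changed sign. A change of sign was counted only where the interval of the main median excluded 0. Where a cause is not given by fewer genes or arrays, the cause was not tested. A floor at the 60th percentile tests fewer genes: it gave 178 genes for KO against WT in ESCs, 864 in MEFs without DOX and 540 for DOX in KO MEFs. A threshold of 1.5 on the log2 scale gave 172, 541 and 336, and 2382 for the Nanog KO array, for which aligned medians gave 2580 and quantile normalization 2595. In limma, leaving out 1 pair gave 0 to 4 genes for genotype, 0 for DOX and 3182 for ESC against MEF, the last also with only the arrays compared. ESC against MEF gave 33 genes with no filter, 26 without a trend and 544 without the block. The fits without the library labelled KO with DOX, added after the data were seen, gave 3194 for ESC against MEF and 912 for DOX. The last sets a single WT array with DOX against the rest, with the spread taken from the other groups, and is no measure of a DOX effect common to both genotypes. The genotype count was 0 in all other fits.

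The pluripotency difference in DOX response was -2.28 over members above the floor (added after the data were seen) and -1.70 with the floor at the 60th percentile. The share of the distance turned to -8.3% for WT MEFs with DOX and became -2.0% for the library labelled KO with DOX and 5.8% for the Nanog KO array with the other genotype's end points. For that array it was 1.6% with aligned medians and 5.3% with quantile normalization. Among list medians whose main interval held a single sign, those that changed sign were Hox genes in ESCs over members above the floor (0.15), pluripotency genes for DOX in KO MEFs with the floor at the 60th percentile (0.12) and 4 lists on the Nanog KO array. With aligned medians these were pluripotency (-0.22), germ cell (-0.23), H3K27 enzymes and Polycomb (-0.43) and partners of Utx (-0.31). Quantile normalization gave -0.16, -0.08, -0.38 and -0.24, and the floor at the 60th percentile gave -1.19 for pluripotency.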

Other observations

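Some imprinted genes differed widely among the MEF libraries, reported as values of single arrays. Phlda2, a maternally expressed growth gene, read 5.69 in WT MEFs without DOX and 11.05 with DOX, near the 10.84 of WT ESCs, while Meg3 read 11.35 and 6.70, Plagl1 10.14 and 6.55, and Dlk1 11.74 and 7.28. Mest, another imprinted gene, read 11.40 in WT MEFs without DOX and 7.58 in the library labelled KO without DOX. Interferon-stimulated genes had a median level of 9.06 on the Nanog KO array, with Oas2 at 9.62 and Irf7 at 9.25, against 7.69 in WT MEFs without DOX and at most 6.74 in the other MEF libraries. Against WT MEFs without DOX, the same list differed by a median of 1.47, with 18 of 22 members 2-fold or more higher beside a shift of 0.73 for the median gene. Macrophage genes differed by a median of -0.56 in that comparison, with 6 of 17 members 2-fold or more lower and 0 higher.

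Most of the remaining lists had small median differences between KO and WT in ESCs. Polycomb repressive complex 2 and the H3K27 enzymes had a median of 0.00, partners of Utx in the MLL3/MLL4 complex 0.16, developmental regulators outside Hox -0.07, Hox genes -0.19 (percentile 0.15, but 0.15 over the 3 of 27 members above the floor), germ cell genes 0.08, p53 targets -0.11, and interferon-stimulated genes -0.07. Imprinted genes, at -0.33 with 3 of 15 members above the floor lower, lay at percentile 0.0 of the random lists, as did the Y-linked genes with Xist, at -2.92 with 3 of 3 lower. The reprogramming factors had 0.22. Lists of other cell types had medians of -0.01 (leukocyte and macrophage), -0.10 (endothelial), -0.29 (muscle, percentile 0.43), 0.06 (neural and glial) and -0.19 (chondrocyte, osteoblast and adipocyte). Among the enzymes, Ezh2 read 10.98 and 11.19, Suz12 11.05 and 11.03, and Eed 10.45 and 10.81. In MEFs with DOX, endothelial genes had a median of -0.95 in KO minus WT as labelled, and the list of chondrocyte, osteoblast and adipocyte genes 1.23.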
